A study of Mus musculus with 29 samples.

How the data were processed

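RNA of mouse ES cells of the 129/Ola strain had been made into Illumina libraries, per the labels' protocols. The 20 RNA-seq libraries formed 10 groups of 2: wild type, Trim66 KO1 and Trim66 KO2; GFP vector and GFP-TRIM66; a control, Dax1 hairpin 1 and Dax1 hairpin 2; and a control and a double knockdown of Dax1 and Dux. Another 9 samples, of chromatin immunoprecipitation, were not analysed here.

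The deposited tables, 1 per experiment, hold raw read counts per gene and per subfamily of transposable elements, per the file headers, and all values are whole numbers. Per the submitters' processing notes, the tools used for the series were Trim Galore, Bowtie2, MACS2, DiffBind, deepTools, HISAT2 2.1.0 and Cufflinks 2.2.1, with the mm10 genome. The counting tool, the gene annotation, strandedness and the rule for reads that map to several places are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads shared by near-identical copies, such as the Zscan4 and Usp17l families, can be divided in ways the tables do not show. Of the gene features with 100 or more counts, 12 had counts identical to those of another.

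Each table had 25574 features, 24394 genes and 1180 transposable element subfamilies. Gene names that spreadsheet software had turned into dates (27 features) were kept in the library totals. Totals ranged from 12483949 to 17365296 counts. Positions came from a reference gene table of GRCm38.p6, the build that mm10 denotes, where 24273 gene names (99.5%) were found by symbol or synonym.

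Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes and elements were fitted together, features with low counts were removed with filterByExpr, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test. Adjusted p is the Benjamini-Hochberg value over all genes and elements tested in a comparison, and a gene was called higher or lower at an adjusted p under 0.05 with no minimum fold change. The knockout and knockdown effects were the mean of both lines, or of both hairpins, against their controls, with separate groups in the fit. Lines and hairpins were also compared directly. The Dax1 knockdown effect was compared with the double knockdown effect as an interaction in a fit of all 20 libraries. CPM values are normalized by TMM, and spreads are the SD over libraries.

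For a group with 0 counts in all libraries, fold changes are lower bounds computed against 3 counts over the group. For 1 to 3 counts the ratio of CPM is given with a 95% exact binomial interval, which covers counting error alone, as do the bounds.

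The 20 gene lists and 11 element lists were written before the data were examined, from general knowledge of the field: genes of the 2-cell-like state (69 written, 59 in the tables), its regulators, naive pluripotency, formative and primed epiblast, primitive endoderm, trophectoderm, germ layers, germline genes held methylated in most other cells, oocyte and maternal-effect genes, p53 targets, interferon-stimulated genes, integrated stress response, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis, mitosis, fibroblast genes as a possible other cell type, imprinted genes, retroelement silencing, genes linked to DAX1, and MERVL, other MT2, MaLR, IAP, ETn and MusD, ERVK, ERV1, young LINE-1, all LINE-1, SINE B1 and B2 and satellite elements. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM. The prior count was 2 and the preset correlation 0.01. Camera with an estimated correlation and fry were run beside camera with the preset. Camera with an estimated correlation lost calls even where the estimate lay below the preset. A lost call is therefore not read as correlation between genes. Of the 3 members of the MERVL list, MERVL-int and MT2_Mm were reported by member, and the last is not named. Calls within a list were also adjusted over the list alone. Overlaps of calls were tested with a one-sided Fisher's exact test. Of the genes raised or lowered in 1 experiment, sets were made and tested by camera in the others.

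Genes could be named by a rule written before the data were examined: Trim66, Nr0b1, Dux, MERVL-int and MT2_Mm; Zscan4c, Zscan4d, Zfp352, Tcstv1, Tcstv3, Pou5f1, Sox2, Nanog and Zfp42 where tested; the 8 largest rises and 6 largest falls among called genes with a mean of at least 2 CPM and every treated library on the same side of every control library, gene models left out; up to 4 called members of each list with the smallest adjusted p, 6 for the 2-cell list; and the 4 largest differences each way between lines, hairpins or experiments. The text names a subset of the genes the rule gives, chosen after their values were seen, and a few genes are not reported here.

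Chromosome medians were taken over genes above a log2 CPM of 3. Chance sharing through common controls was estimated from 20 simulated sets with seed 1. The edgeR fit was tested on counts simulated with known changes from means of the same libraries, without rates by count level. A change of 1.5-fold, 2-fold and 4-fold was recovered for 57.6%, 85.1% and 100% of changed genes in the knockout comparison (14834 features), 1.52%, 4.48% and 58.2% in the overexpression (14796), 86.4%, 92.5% and 100% in the Dax1 knockdown (14629), 6.06%, 38.8% and 92.4% in the double knockdown (14182), and 3.03%, 43.3% and 77.6% for the difference of both knockdowns (15639), with 9, 4, 8, 18 and 6 false calls.

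Alternatives set before the data were examined were RLE and upper quartile scaling, no filter on low counts, DESeq2 1.42.0 with its Wald test, a replicate block, genes without elements, a minimum fold change of 2, lines or hairpins pooled into 1 group, each library left out in turn, and for lists an estimated correlation and fry. Leaving out chromosomes 1, 15, 19 and Y, and a crossed pairing of replicates, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.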

Results

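RNA-seq read counts were analysed for 20 libraries of mouse embryonic stem (ES) cells of the 129/Ola strain, grown on gelatin in medium with serum. They formed 4 experiments with 2 libraries in each group. The Trim66 knockout experiment held a wild-type group and the lines KO1 and KO2 labelled as Trim66 knockouts, where Trim66 encodes a tripartite motif protein of the chromatin-associated TRIM24/28/33 family. The overexpression experiment set cells carrying a GFP vector against cells expressing GFP-TRIM66. The Dax1 experiment set a control against cells with hairpin 1 (sh1) or hairpin 2 (sh2) against Dax1, the common name of Nr0b1, which encodes an orphan nuclear receptor that acts mostly as a corepressor. The double knockdown experiment set a control against a double knockdown of Dax1 and of Dux, which encodes the homeobox factor that switches on genes of the 2-cell embryo. The 2-cell-like state, named in the title of the series, is a rare state of ES cells in which genes and retroelements of the 2-cell embryo are transcribed.

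Each table listed 24394 genes and 1180 subfamilies of transposable elements. Total counts ranged from 12483949 to 17365296 per library. The share of counts in transposable elements was 9.61% and 7.82% in the GFP vector libraries and 4.87% and 4.17% in the GFP-TRIM66 libraries, against 6.30% to 7.57% in the knockout experiment, 5.19% to 6.14% in the Dax1 experiment and 4.47% to 5.19% in the double knockdown experiment. No label says that replicates came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. The biological coefficient of variation was 0.102 in the knockout experiment, 0.283 in the overexpression, 0.0392 in the Dax1 knockdown and 0.189 in the double knockdown. In data simulated from the same libraries, a 2-fold change was recovered for 85.1%, 4.48%, 92.5% and 38.8% of changed genes in the same order, and a 4-fold change for 100%, 58.2%, 100% and 92.4%.

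Trim66 (chromosome 7, 109449001 to 109516759, GRCm38.p6) had 11 and 15 counts in the wild-type libraries, 35 and 38 in the KO1 libraries and 33 and 48 in the KO2 libraries. Its level was 0.898 ± 0.154 CPM (counts scaled to library size; SD, n = 2) in wild type and 2.64 ± 0.123 CPM (SD, n = 4) in the libraries labelled knockout, a log2 fold change of 1.55 (SE 0.293, adjusted p = 0.00483). The count of the targeted gene thus went against the label, and the tables do not say which part of the gene was targeted. The lines are therefore called the libraries labelled knockout, and each direction given for them rests on that label. With GFP-TRIM66 it rose from 1.74 ± 0.0844 to 210 ± 19.1 CPM (SD, n = 2 each), a log2 fold change of 6.90 (SE 0.284, adjusted p = 5.39e-04).

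Nr0b1 (chromosome X, 86191775 to 86195947) fell with both hairpins, from 154 ± 5.61 CPM (SD, n = 2) to 69.1 ± 10.1 CPM (SD, n = 4), with a log2 fold change of -1.17 (SE 0.0484, adjusted p = 7.6e-17) that was -1.35 for sh1 and -0.99 for sh2. In the double knockdown it went from 41.5 ± 11.2 to 22.3 ± 3.13 CPM (SD, n = 2 each), a log2 fold change of -0.90 that did not pass the test (adjusted p = 0.275). Dux had 0 counts in both controls of the double knockdown and 2 and 0 counts in the double knockdown, so its knockdown could not be assessed. In the libraries labelled Trim66 knockout Nr0b1 was at a log2 fold change of 0.09 (adjusted p = 0.466), and with GFP-TRIM66 at 1.21 (adjusted p = 0.286), from 65.5 ± 40.1 to 151 ± 73.6 CPM.

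**Figure D1:**
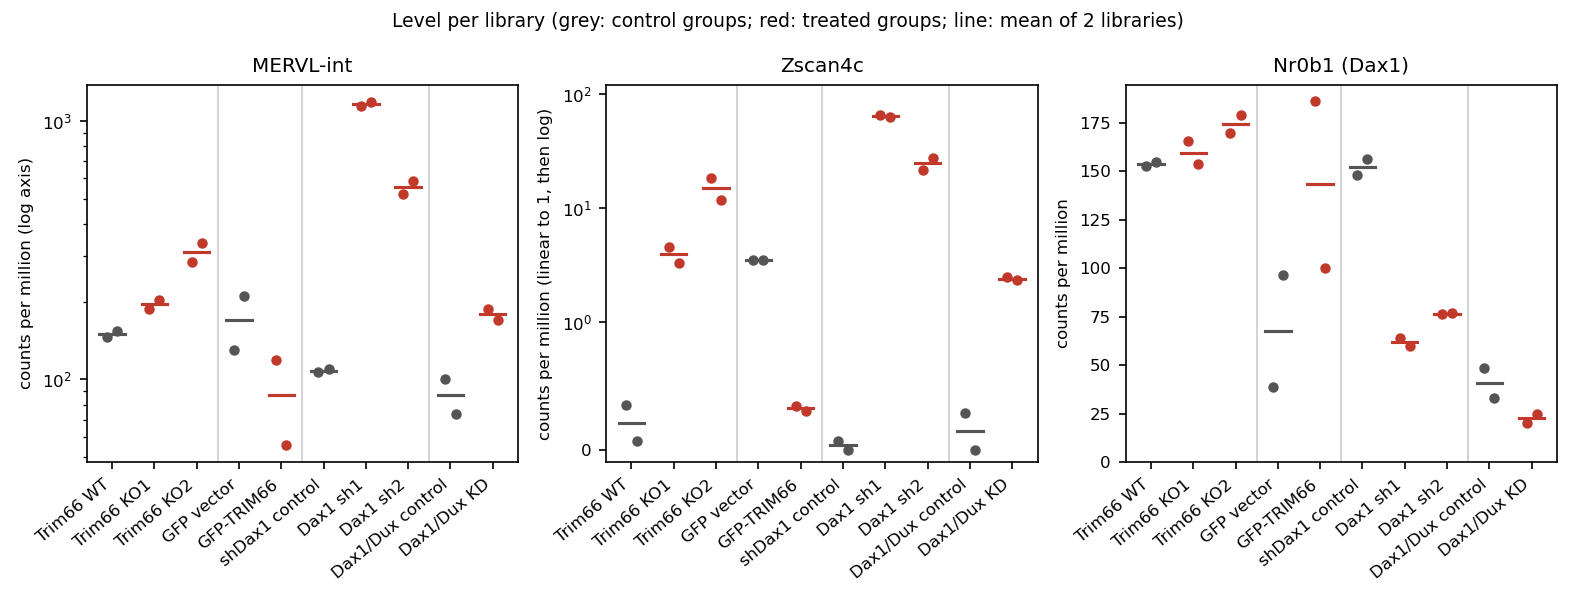
Level in CPM of MERVL-int (log axis), Zscan4c (linear to 1, then log) and Nr0b1 (linear axis) in each of the 20 libraries, with grey points for control groups, red points for treated groups and a line at the mean of the 2 libraries of a group. MERVL-int and Zscan4c were highest in the sh1 libraries, and both libraries of every treated group of the knockout and knockdown experiments lay above their controls.

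The comparison of the lines labelled Trim66 knockout with wild type asked how the transcriptome, and the 2-cell programme in particular, differed between the libraries labelled knockout and wild type. Genes of the 2-cell embryo were higher in the libraries labelled knockout. Of 33 such genes with enough counts, 28 rose and 0 fell, and their summed level went from 29.6 to 153 CPM. Zscan4c (chromosome 7, 11005745 to 11010547), of the Zscan4 family that acts in telomere maintenance, rose from 0.213 ± 0.206 CPM (SD, n = 2) to 9.37 ± 6.84 CPM (SD, n = 4), a log2 fold change of 5.13 (SE 0.475, adjusted p = 9.9e-05). MERVL-int, the internal part of the endogenous retrovirus transcribed at the 2-cell stage, rose from 152 ± 6.05 to 252 ± 69.1 CPM (log2 fold change 0.69, SE 0.0931, adjusted p = 7.68e-04), and its promoter element MT2_Mm by 0.41 (adjusted p = 0.00801). Of the 3 members of the MERVL list 2 rose and 0 fell, against 2 and 1 at an unadjusted p under 0.05. Genes of chromosome 1 were lower in the libraries labelled knockout, as given below.

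Within the 2-cell list, Zscan4d rose by 4.42 (adjusted p = 1.02e-04), Zscan4f by 4.81 (adjusted p = 1.39e-05), Zscan4b by 4.28 and Zscan4a by 3.66 on the log2 scale. The gene models Gm8994 and Gm5662 rose by 5.62 and 4.36. Gm8300 had 2 counts in wild type and 389 in the libraries labelled knockout, a ratio of 98.6 with a 95% counting interval of 27.1 to 817. Zfp352, a zinc finger gene of the early embryo, had 0 counts in wild type and was at least 7.27-fold higher (adjusted p = 0.0104). Dux had 0 and 1 counts in wild type, 1 and 6 in KO1 and 15 and 15 in KO2, a ratio of 18.8 with an interval of 3.16 to 761 (adjusted p = 0.0378). The call of Dux was lost in 5 of 13 alternatives, with an adjusted p up to 0.269, and that of Zfp352 in 3, with an adjusted p up to 0.0997. Adjusted over the list alone, 29 genes rose. The median log2 fold change of the list was 4.36, or 3.80 with the 5 genes at 0 wild-type counts placed at their bound, since a fitted fold change of such genes is no bound. The list ranked above other genes by camera (adjusted p = 1.43e-17; adjusted p = 0.0593 with an estimated correlation).

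The 2-cell genes and MERVL were higher in KO2 than in KO1. MERVL-int rose by 0.35 in KO1 and 1.02 in KO2, and the difference of 0.67 passed its own test, as did those of MT2_Mm (0.62), Zscan4c (1.92), Zscan4d (2.64) and Zfp352 (2.00). Of the 2-cell list, 22 of 33 genes were higher in KO2 than in KO1 and 0 lower by the edgeR test.

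Factors of the general pluripotency network stayed near their wild-type level on average. Pou5f1 was at a log2 fold change of -0.12 (adjusted p = 0.667), Sox2 at 0.00 (adjusted p = 0.988), Zfp42 at -0.03 and Nanog at -0.21 (adjusted p = 0.119), where Nanog was -0.53 in KO1 (adjusted p = 0.00385) and 0.11 in KO2. The sign for Sox2, Pou5f1 and Zfp42 turned under some alternatives. Of 40 genes of naive pluripotency, 12 rose and 10 fell, 4 of the latter on chromosome 1 (camera adjusted p = 0.833). Tfcp2l1, a naive transcription factor on chromosome 1, fell by 1.35 on the log2 scale (adjusted p = 4.54e-05). Dppa3, a maternal factor also found in naive cells, rose by 3.51, and Lefty2, an inhibitor of Nodal signalling that lies on chromosome 1, by 1.07. Of 24 formative and primed epiblast genes, 7 rose and 5 fell (camera adjusted p = 0.106), among them Zic2, a zinc finger factor of the epiblast (2.25, adjusted p = 6.64e-06), the de novo DNA methyltransferase gene Dnmt3b (1.27, adjusted p = 2.36e-05) and the kinase gene Pim2 (1.62).

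Of 23 primitive endoderm genes 15 fell, 2 of them on chromosome 1, and 4 rose, or 16 and 5 adjusted over the list alone (camera adjusted p = 0.00195, and 0.168 as an adjusted p with an estimated correlation; median -0.78). In KO1 15 fell and 5 rose (camera adjusted p = 0.00128, and adjusted p = 0.176 with an estimated correlation). In KO2 6 fell and 2 rose with no call (camera adjusted p = 0.0804). The laminin genes Lama1 and Lamc1, which encode basement membrane subunits, fell by 0.94 and 1.08, the latter on chromosome 1, while the homeobox gene Rhox5 and the lipid carrier gene Apoe rose by 2.51 and 1.28. Of 18 trophectoderm genes 10 rose and 4 fell (camera adjusted p = 0.0115, and adjusted p = 0.196 with an estimated correlation), with the same counts over the list alone. In KO1 10 rose and 3 fell (camera adjusted p = 0.00624, and adjusted p = 0.182 with an estimated correlation). In KO2 5 rose and 3 fell with no call (camera adjusted p = 0.303). In KO2 against KO1 9 were lower and 1 higher (camera adjusted p = 0.00141, and adjusted p = 0.302 with an estimated correlation). The keratin genes Krt18 and Krt8, 2 of the 3 risers on chromosome 15, rose by 1.78 and 1.10, where Krt8 was 2.39 in KO1 and -0.19 in KO2. Tfap2c, a transcription factor of trophectoderm and germ cells, rose by 1.10. Of 8 oocyte and maternal-effect genes 6 rose and 1 fell (camera adjusted p = 0.00206, and adjusted p = 0.168 with an estimated correlation; same counts over the list alone), including the zona pellucida gene Zp3 (1.60) and the maternal complex gene Ooep (0.53).

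Of 31 glycolysis and hypoxia genes 18 rose and 1 fell, or 21 and 2 over the list alone (camera adjusted p = 4.14e-07, and adjusted p = 0.168 with an estimated correlation; median 0.46), with Bnip3, a mitophagy gene induced by low oxygen, at 1.62 (adjusted p = 6.93e-05), Ndrg1, a hypoxia-induced gene on chromosome 15, at 1.02 and the glycolytic enzyme gene Tpi1 at 0.63. Of 35 integrated stress response genes 16 rose and 1 fell, or 20 and 2 over the list alone (camera adjusted p = 6.44e-05, and adjusted p = 0.145 with an estimated correlation), with the mTORC1 inhibitor gene Ddit4 at 1.59 and the secreted glycoprotein gene Stc2 at 1.10. In KO1 23 of them rose and 0 fell (camera adjusted p = 3.85e-07, and adjusted p = 0.113 with an estimated correlation). In KO2 5 rose and 2 fell with no call (camera adjusted p = 0.249). Of 33 ribosome biogenesis genes 10 fell and 0 rose, and 5 of the 10 lie on chromosome 1; 13 fell over the list alone, 16 fell and 0 rose at an unadjusted p under 0.05, and DESeq2 gave 10 and 0 (camera adjusted p = 3.83e-04, and adjusted p = 0.145 with an estimated correlation). Ncl, which encodes the nucleolar protein nucleolin, fell by 0.56 and the pre-ribosome factor gene Wdr12 by 0.66, both on chromosome 1. Of 25 cholesterol synthesis genes 4 fell and 0 rose, with the same counts over the list alone, 8 and 0 at an unadjusted p and 3 and 0 by DESeq2 (camera adjusted p = 0.04, and adjusted p = 0.25 with an estimated correlation). This list had no call in KO1 (camera adjusted p = 0.275) and a call in KO2 (camera adjusted p = 0.00389, and adjusted p = 0.265).

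Imprinted genes, which are transcribed from a single parental copy, rose in 12 of 33 cases and fell in 2, or 15 and 2 over the list alone (camera adjusted p = 3.7e-04, and adjusted p = 0.145 with an estimated correlation). The paternally transcribed gene Mest rose by 2.43 (adjusted p = 5.95e-06) and Impact by 0.94, while the growth factor receptor adaptor gene Grb10 fell by 2.03 (-3.34 in KO1 and -0.71 in KO2) and Zdbf2, on chromosome 1, by 1.14. Of 17 fibroblast genes, tested as markers of another cell type that ES cell culture can hold, 8 rose and 2 fell, or 9 and 2 over the list alone (camera adjusted p = 0.00441, and adjusted p = 0.26 with an estimated correlation). They were called in KO1 (9 and 2; camera adjusted p = 0.00152, and adjusted p = 0.227) and not in KO2 (4 and 2; camera adjusted p = 0.148). The intermediate filament gene Vim rose by 1.06, while the fibronectin gene Fn1, on chromosome 1, fell by 1.01. Among 6 young LINE-1 subfamilies 4 rose and 0 fell, or 5 and 0 over the list alone and at an unadjusted p, and 4 and 0 by DESeq2 (camera adjusted p = 4.8e-04, and adjusted p = 0.274 with an estimated correlation), with L1Md_A at 0.99 and L1Md_T at 0.93. In KO1 the young LINE-1 had a median of 0.40 and no call (camera adjusted p = 0.0954), and in KO2 a median of 1.03 (camera adjusted p = 8.57e-07, and adjusted p = 0.265 with an estimated correlation). Of the 6, 5 were higher in KO2 than in KO1. Of 5 ETn and MusD elements 3 rose and 0 fell, or 4 and 0 over the list alone and at an unadjusted p, and 3 and 0 by DESeq2 (camera adjusted p = 0.04, and adjusted p = 0.298 with an estimated correlation). ETn and MusD were called in KO1 (camera adjusted p = 0.0456, and adjusted p = 0.368) and not in KO2 (camera adjusted p = 0.0804).

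Other lists gave no camera call on average over both lines. Known regulators of the 2-cell-like state rose in 5 and fell in 7 of 37 cases, germ layer genes in 7 and 3 of 25, methylation-dependent germline genes in 10 and 6 of 29, p53 targets in 7 and 5 of 29, interferon-stimulated genes in 4 and 1 of 18, and nuclear receptors and cofactors linked to DAX1 in 4 and 6 of 22. The germline genes went opposite ways, with 4 higher and 12 lower in KO1 (camera adjusted p = 0.0218, and adjusted p = 0.679 with an estimated correlation) and 16 higher and 0 lower in KO2 (camera adjusted p = 3.7e-09, and adjusted p = 0.343). Called in 1 line alone were p53 targets (higher in KO1; camera adjusted p = 0.0483, and adjusted p = 0.245), formative genes (higher in KO2; 0.0326, and adjusted p = 0.412), mitotic genes (higher in KO2; 7.46e-04, and adjusted p = 0.412), all LINE-1 (lower in KO1; 0.00766, and adjusted p = 0.778), SINE B1 and B2 (lower in KO1; 0.0152, and adjusted p = 0.763) and ERVK elements (higher in KO2; 0.0152, and adjusted p = 0.521). Retroelement silencing genes rose in 6 and fell in 0 of 37 cases, including Dnmt3l, a cofactor of de novo DNA methylation (1.20), and mitotic genes rose in 1 and fell in 0 of 30; at an unadjusted p these were 7 and 4, and 4 and 1, and DESeq2 gave 6 and 0, and 1 and 0. The interferon-stimulated gene with the lowest adjusted p was Ifitm3, which encodes an antiviral membrane protein, at 2.23 (adjusted p = 3.16e-06). ERVK elements rose in 21 and fell in 3 of 258 cases, MaLR elements in 3 and 2 of 87, intracisternal A particles in 2 and 1 of 22, ERV1 elements in 2 and 3 of 94, all LINE-1 in 7 and 3 of 123 and satellites in 1 and 0 of 5. Neither the 5 other MT2 elements nor the 21 SINE B1 and B2 subfamilies had a call (0 and 1 at an unadjusted p, and 0 by DESeq2).

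Over all 14189 genes tested, 1872 were higher and 1587 lower in the libraries labelled knockout, and of 897 transposable elements 45 were higher and 27 lower. KO1 alone gave 2587 higher and 2035 lower genes and KO2 936 and 792. The largest rises by the naming rule were those of the smooth muscle actin gene Acta2 (0 counts in wild type, at least 81.0-fold higher; chromosome 19), Efhc2, an EF-hand gene on chromosome X (5.60, adjusted p = 3.53e-06), the Y-linked zinc finger gene Zfy1 (4.33, adjusted p = 0.00342), Aass, of lysine breakdown (4.26, adjusted p = 8.54e-06), and the Zscan4 genes above. Among the largest falls were those of the ion channel gene Trpa1 (-2.46, chromosome 1), Frmd4b (-2.17), the cyclin gene Ccnd2 (-2.15, adjusted p = 2.67e-06), Grb10 (-2.03) and the histidine-degrading enzyme gene Hal (-2.03).

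Genes of chromosome 1 had a median log2 fold change of -0.55 (-0.62 in KO1 and -0.49 in KO2): 431 of 763 fell and 31 rose. With the chromosome divided into 10 stretches, the last 2 lay at -0.12 and -0.03 in KO2 and at -0.51 and -0.65 in KO1. The wild-type libraries held chromosome 1 at 0.56 and 0.53 above the GFP libraries, relative to other autosomes, and the libraries labelled knockout at -0.08 to 0.09. In KO1 the genes of chromosome 15 lay at a median of 0.27, and of 5 Y-linked genes 4 were higher in the libraries labelled knockout. Without chromosomes 1, 15, 19 and Y, an alternative chosen after seeing the data, 1642 genes were higher and 1083 lower. Treating KO1 and KO2 as samples of 1 group gave 276 higher and 264 lower genes and 14 of the 2-cell genes, and ended the calls of MERVL-int (adjusted p = 0.127) and MT2_Mm (adjusted p = 0.282). Without wild-type replicate 1 the counts were 674 and 528, and without wild-type replicate 2 they were 689 and 703.

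**Figure D2:**
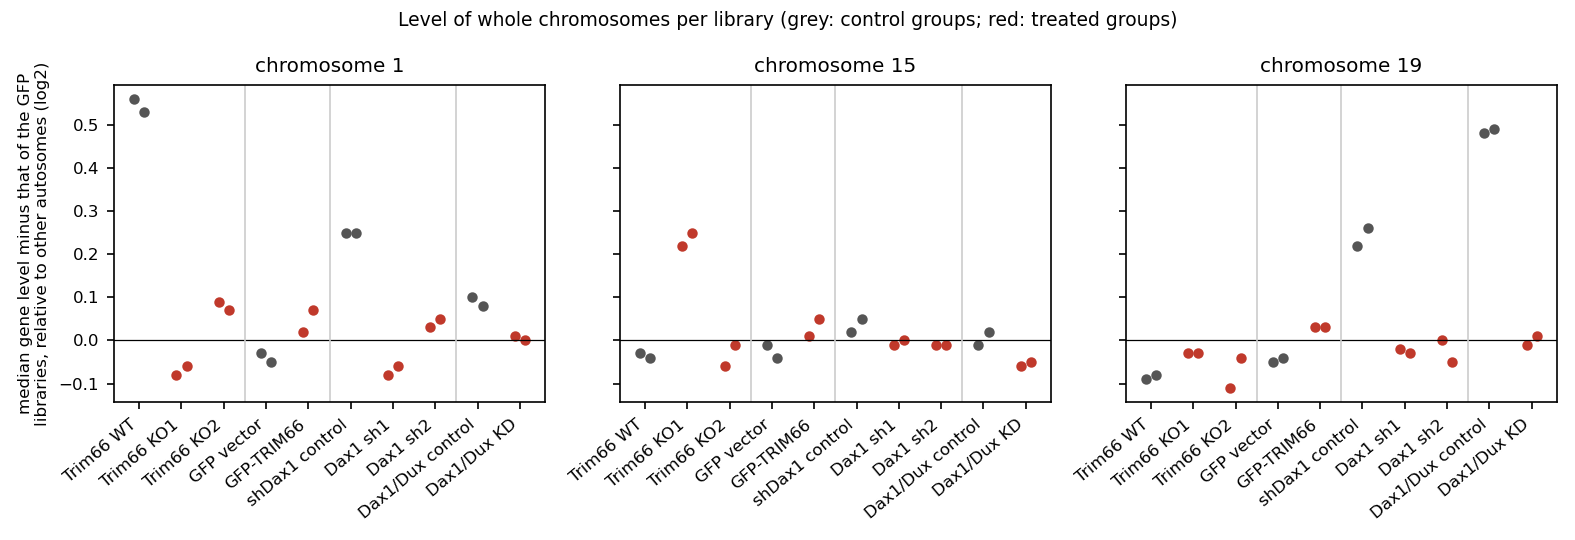
Median level of the genes of chromosomes 1, 15 and 19 in each library, as log2 difference from the GFP libraries and relative to other autosomes, with grey points for control groups and red points for treated groups; the GFP libraries lie near 0 by construction. Chromosome 1 stood at 0.56 and 0.53 in the wild-type libraries, and chromosome 19 at 0.48 and 0.49 in the controls of the double knockdown.

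KO2 and KO1 differed in 1465 genes that were higher and 1941 that were lower in KO2, with 58 and 13 transposable elements. Among the largest differences were those of Xlr3a (5.27), an X-linked gene, the potassium channel gene Kcnj3 (3.72) and the cytochrome P450 gene Cyp2b23 (3.45) on the higher side, and on the lower side Trpc5os (-5.02), an antisense gene whose reads cannot be parted from its partner without strand, Acta2 (-3.57), the G protein gene Gna14 (-3.51) and the mesothelin gene Msln (-3.50). Genes called in KO1 and in KO2 shared 610 higher and 500 lower, against 171 and 114 for independent lists, and unchanged groups simulated against the same wild-type libraries shared 0.15 and 0.05. Without chromosomes 1, 15, 19 and Y, 551 higher and 228 lower genes were shared, against 153 and 55.3. Fold changes of both lines correlated at 0.583 across genes, against 0.501 in the simulation, with a covariance of 0.12 against 0.0131. Genes are not independent replicates, and with 2 shared controls that cannot be split part of the excess may come from them. Without KO1 replicate 2 the difference between the lines counted 366 and 610 genes, and without KO2 replicate 2 2362 and 2977.

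The overexpression experiment asked what changed with more TRIM66. Apart from Trim66 itself, edgeR called 1 higher and 1 lower gene at this spread. Same-numbered libraries of the groups deviated in opposite directions (correlation -0.641). The fit did not model this. Inhbb (chromosome 1, 119415463 to 119422248), which encodes the activin beta-B subunit, rose from 43.5 ± 5.19 to 263 ± 16.8 CPM (SD, n = 2 each), a log2 fold change of 2.59 (SE 0.226, adjusted p = 0.0353). Wdr38 (chromosome 2, 38998309 to 39001584), a WD repeat gene, fell from 29.8 ± 0.267 to 0.334 ± 0.206 CPM, a log2 fold change of -6.44 (SE 0.481, adjusted p = 0.0182). The 2-cell genes were lower on average, with no single call over all genes tested.

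All 21 tested genes of the 2-cell list had a negative log2 fold change, with a median of -2.57 and a summed level that went from 96.5 to 31.3 CPM. The edgeR test called 0 of them, against 18 lower adjusted over the list alone, 18 lower at an unadjusted p under 0.05 and 8 lower by DESeq2. As a list they ranked below other genes (camera adjusted p = 7.13e-14; adjusted p = 0.477 with an estimated correlation). Zscan4c was at -3.29 (adjusted p = 0.163), Zscan4d at -1.92 (adjusted p = 0.207), MERVL-int at -0.83 (adjusted p = 0.368; 165 to 92.4 CPM) and MT2_Mm at -0.81 (adjusted p = 0.234). With 1 library left out at a time, MERVL-int ranged from -1.58, without GFP-TRIM66 replicate 1, to -0.34. ERVL elements as a class had a median of -1.09 and old, inactive elements (L2, MIR, CR1, hAT and TcMar) of -1.13. With all libraries, MERVL-int and MT2_Mm thus fell no more than these classes. Dux had 4 and 11 counts with the vector and 0 with GFP-TRIM66, at least 5.99-fold lower, and was too low to be tested. Pou5f1, Sox2, Nanog and Zfp42 were at 0.39, 0.51, 0.14 and 0.47, none of them past the threshold (adjusted p = 0.391, 0.299, 0.753 and 0.477).

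Transposable elements were lower as whole classes with GFP-TRIM66, and none of the 910 subfamilies passed the edgeR test on its own, against 528 lower and 2 higher at an unadjusted p and 165 lower and 1 higher by DESeq2. LINE-1 elements had a median of -1.18 (79 of 125 lower over the list alone; camera adjusted p = 2.96e-32), MaLR elements of -1.09 (60 of 88; 1.02e-27), ERVK elements of -1.06 (105 of 257; 2.03e-33), SINE B1 and B2 of -1.05 (19 of 21; 1.13e-14), ERV1 elements of -0.92 (0 of 94; 6.5e-12), other MT2 elements of -0.72 (4 of 5; 2.98e-04) and ETn and MusD of -0.61 (3 of 5; 0.00449), and intracisternal A particles lay lower too (1 of 22; 2.49e-08). With an estimated correlation each had an adjusted p = 0.477, except ETn and MusD with adjusted p = 0.511. Young LINE-1 (camera adjusted p = 0.344) and satellites (0.0796) gave no call. The share of counts in elements moved with this contrast, as given for the libraries above.

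Of the gene lists, p53 target genes were lower (median -0.77, 11 of 30 lower over the list alone, 14 at an unadjusted p and 8 by DESeq2; camera adjusted p = 3.11e-07, and adjusted p = 0.477 with an estimated correlation). Formative and primed genes were higher (median 0.73; 2.44e-06), as were ribosome biogenesis genes (0.63; 7.1e-09), 2-cell regulators (0.31; 4.79e-05), retroelement silencing genes (0.26; 0.00114), naive genes (0.34; 0.0015), integrated stress genes (0.33; 0.00279), germ layer genes (0.61; 0.00449) and mitotic genes (0.20; 0.031). Germline genes (-0.70; 0.0015) and glycolysis and hypoxia genes (-0.27; 0.013) were lower. Each value after a median is a camera adjusted p, and with an estimated correlation no list kept its call, with an adjusted p = 0.477 to 0.68. Over the list alone, 5 formative, 6 germ layer, 3 naive and 0 of 33 ribosome biogenesis genes were higher, and 12 of the last at an unadjusted p and 2 by DESeq2. Primitive endoderm, trophectoderm, oocyte, interferon, cholesterol, fibroblast and imprinted genes and the genes linked to DAX1 gave no camera call.

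Over 14168 genes, 2 were higher and 1 lower, against 1153 and 836 at an unadjusted p and 288 and 111 by DESeq2. Left-out libraries moved this count, with values given with the processing below.

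The Dax1 knockdown asked whether the 2-cell programme differed in libraries with lower Dax1. Controls and hairpin libraries also differed in RNA of Y-linked genes and of chromosomes 1 and 19, as given below. Effects of lower DAX1 thus cannot be told apart from other differences between these libraries. With both hairpins the 2-cell genes rose by the largest amounts of the 4 experiments. Of 45 genes tested, 43 rose and 0 fell, and the summed level of the list went from 18.5 to 675 CPM. MERVL-int rose from 109 ± 1.61 CPM (SD, n = 2) to 848 ± 333 CPM (SD, n = 4), a log2 fold change of 2.87 (SE 0.0489, adjusted p = 1.83e-25), and MT2_Mm by 2.40 (adjusted p = 8.64e-19). Zscan4c had 1 count in the controls and 2465 in the knockdown, a ratio of 1310 with an interval of 234 to 51600. Dux had 0 counts in both controls, 49 and 54 with sh1 and 14 and 26 with sh2, at least 25.2-fold higher.

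Further 2-cell genes followed. Zscan4d was at a ratio of 492 (168 to 2390), Zscan4b at 758 (210 to 6260), and Zscan4f rose by 8.25 on the log2 scale (adjusted p = 1.77e-23). Among genes at 0 counts in both controls, the deubiquitinase gene Usp17lc was at least 84.5-fold higher, Tmem92, a transmembrane protein gene, at least 50.5-fold, Zfp352 at least 24.9-fold, and Tcstv3 and Tcstv1, of a family transcribed at the 2-cell stage, at least 22.1-fold and 9.71-fold. Usp17le was at a ratio of 328 (90.6 to 2710) and Gm6763 at 746, with counts identical to those of Gm21312. Reads of near-identical copies can be divided in ways the tables do not show, so the values of single copies are uncertain. The median log2 fold change of the list was 7.40, or 5.66 with 16 genes at their bound, and 43 genes rose over the list alone (camera adjusted p = 3.19e-49, and still adjusted p = 0.0347 with an estimated correlation). DESeq2 called 42 higher and 0 lower, and 43 and 0 passed an unadjusted p. The netrin receptor gene Dcc, which is not on the list, was at least 30.0-fold higher.

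Genes of naive pluripotency were lower with sh1 and not with sh2. Of 40 such genes 26 fell on average over both hairpins, 6 of them on chromosome 1, and 8 rose, or 26 and 9 over the list alone (median -0.24, camera adjusted p = 9.98e-06, and adjusted p = 0.0842 with an estimated correlation). With sh1 5 rose and 31 fell (median -0.45, camera adjusted p = 7.81e-12, and still adjusted p = 0.0378 with an estimated correlation). With sh2 16 rose and 12 fell (median 0.04, camera adjusted p = 0.301). Fibroblast genes also split by hairpin, with 15 higher and 1 lower with sh1 and 3 and 10 with sh2, as given below. Tfcp2l1 fell by 1.18 (chromosome 1) and the orphan nuclear receptor gene Esrrb by 0.79 (-1.28 with sh1 and -0.29 with sh2), while Nodal, which encodes a TGF-beta family ligand, rose by 1.13. Pou5f1 was at 0.00 (adjusted p = 0.979), with a sign that turned under RLE scaling, no filter, DESeq2 and 3 left-out libraries. Sox2 fell by 0.33 (adjusted p = 7.71e-08), Nanog by 0.24 (-0.63 with sh1 and 0.15 with sh2) and Zfp42 by 0.14 (-0.46 and 0.18). Of 26 formative and primed genes 11 rose and 6 fell (camera adjusted p = 0.0658), with Pim2 at 1.70, the POU factor gene Pou3f1 at 0.75 and the homeobox gene Otx2 at -0.66.

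Targets of p53, the stress-induced tumour suppressor, rose together. Of 29, 25 rose and 0 fell, or 27 and 0 over the list alone and at an unadjusted p and 23 and 0 by DESeq2 (median 0.38, camera adjusted p = 3.01e-16, and adjusted p = 0.0358 with an estimated correlation). Plk2, a polo-like kinase gene, rose by 0.97, Perp, an effector of p53-dependent cell death, by 0.85 and Trp53inp1, a p53-inducible stress gene, by 0.62. Of 35 integrated stress genes 23 rose and 3 fell, or 24 and 3 over the list alone (camera adjusted p = 7.72e-10, and adjusted p = 0.0866 with an estimated correlation), among them Ddit4 (0.63), the gluconeogenic enzyme gene Pck2 (0.58), the folate cycle gene Mthfd2 (0.49) and Asns, for asparagine synthesis (0.45). Of 30 mitotic genes 16 fell and 0 rose, the same over the list alone, 18 and 0 at an unadjusted p and 15 and 0 by DESeq2 (camera adjusted p = 1.02e-06, and adjusted p = 0.0842 with an estimated correlation). The spindle motor gene Kif11, on chromosome 19, fell by 0.57, the kinetochore gene Cenpf, on chromosome 1, by 0.51 and the topoisomerase gene Top2a by 0.38.

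Of 31 imprinted genes 13 rose and 1 fell, or 14 and 1 over the list alone (camera adjusted p = 4.23e-04, and adjusted p = 0.111 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1c at 0.97, Snrpn, of the splicing machinery, at 0.70, Grb10 at 0.66 and Phlda2, a placental growth regulator, at -0.65. Of 30 germ layer genes 13 rose and 4 fell, or 14 and 4 over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.283 with an estimated correlation), and of 28 germline genes 10 rose and 4 fell with the same counts over the list alone (0.0278, and adjusted p = 0.328 with an estimated correlation). These calls were not shared by both hairpins. Germ layer genes were 19 higher and 3 lower with sh1 (camera adjusted p = 3.33e-04, and adjusted p = 0.0859 with an estimated correlation) and 7 and 4 with sh2 (camera adjusted p = 0.899), and 3 were higher and 16 lower with sh2 than with sh1. Fibroblast genes split in the same way, as given below. Imprinted genes were 17 and 2 with sh1 (camera adjusted p = 2.78e-06, and adjusted p = 0.0542) and 9 and 6 with sh2 (camera adjusted p = 0.343). Germline genes were 9 and 3 with sh1 (camera adjusted p = 0.376) and 12 and 2 with sh2 (camera adjusted p = 4.44e-04, and adjusted p = 0.349). All 6 young LINE-1 subfamilies rose, by every count made (camera adjusted p = 5.66e-08, and adjusted p = 0.283 with an estimated correlation; median 0.61), with L1Md_T at 0.71 and L1Md_A at 0.64. All LINE-1 rose in 34 and fell in 5 of 119 cases (4.23e-04, and adjusted p = 0.54 with an estimated correlation), ERVK elements in 53 and 6 of 251 (2.5e-04, and adjusted p = 0.378), with RLTR45-int at 1.41, and intracisternal A particles in 8 and 1 of 22 (0.0191, and adjusted p = 0.328). Over the lists alone these were 34 and 5, 51 and 4, and 8 and 1. All LINE-1 were 21 and 10 with sh1 (camera adjusted p = 0.243) and 45 and 0 with sh2 (camera adjusted p = 5.69e-09, and adjusted p = 0.414). ERVK elements were 49 and 13 with sh1 (camera adjusted p = 0.0711) and 61 and 5 with sh2 (camera adjusted p = 2.98e-07, and adjusted p = 0.36).

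The remaining lists gave no camera call on average over both hairpins. 2-cell regulators rose in 5 and fell in 14 of 37 cases, with the activators Dppa2 and Nelfa at 0.53 and 0.46. The counts were 7 and 1 of 22 for primitive endoderm, 4 and 5 of 20 for trophectoderm, 8 and 3 of 22 for interferon-stimulated genes, 2 and 3 of 25 for cholesterol synthesis, 9 and 12 of 31 for glycolysis and hypoxia, 4 and 13 of 33 for ribosome biogenesis with 5 of the 13 on chromosome 1 and 3 on chromosome 19, 10 and 3 of 20 for fibroblast genes and 8 and 8 of 23 for the genes linked to DAX1. The hairpins had camera calls in opposite directions in 3 of these lists. Fibroblast genes rose in 15 and fell in 1 of 20 cases with sh1 (camera adjusted p = 1.42e-07, and adjusted p = 0.0859 with an estimated correlation) and in 3 and 10 with sh2 (camera adjusted p = 0.0116, and adjusted p = 0.356). Trophectoderm genes rose in 9 and fell in 4 of 20 cases with sh1 (camera adjusted p = 0.019, and adjusted p = 0.173) and 1 and 10 with sh2 (camera adjusted p = 2.5e-04, and adjusted p = 0.209). SINE B1 and B2 lay lower with sh1 (camera adjusted p = 0.0435, and adjusted p = 0.702) and higher with sh2 (camera adjusted p = 2.23e-05, and adjusted p = 0.422). Called with sh1 alone were interferon-stimulated genes (12 higher and 3 lower; camera adjusted p = 0.0178, and adjusted p = 0.173), 2-cell regulators (5 and 19; 0.00494, and adjusted p = 0.117) and ribosome biogenesis (2 and 15; 0.00504, and adjusted p = 0.294), against 1 and 3, 6 and 9, and 7 and 4 with sh2 (camera adjusted p = 0.393, 0.745 and 0.612). Called with sh2 alone were MaLR elements (27 and 2; 1.91e-04, and adjusted p = 0.422), ERV1 elements (17 and 2; 0.00399, and adjusted p = 0.414) and other MT2 elements (0.0341, and adjusted p = 0.349). Of 7 oocyte and maternal genes 1 rose and 3 fell, with Zp3 at 1.51 and, among the subcortical maternal complex genes, Ooep at -0.90 and Khdc3 at -0.94 (-2.28 with sh1 and 0.40 with sh2). Retroelement silencing genes rose in 10 and fell in 12 of 37 cases, with Dnmt3l at 0.86 and Hells, a chromatin remodeller gene on chromosome 19, at -0.36. MaLR elements rose in 19 and fell in 6 of 87 cases, other MT2 elements in 2 and 0 of 5 with MT2B1 at 1.39, ERV1 elements in 17 and 2 of 84 with RLTR6B_Mm at 1.86, SINE B1 and B2 in 2 and 0 of 21, ETn and MusD in 3 and 1 of 5 and satellites in 2 and 2 of 5 with GSAT_MM at 1.24. For MT2 and SINE elements an unadjusted p gave the same counts and DESeq2 gave 1 and 0, and 2 and 0.

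Over all 14017 genes, 2348 were higher and 2609 lower, and of 848 elements 150 were higher and 36 lower. The largest falls were those of the corepressor gene Skor1 (-2.86, adjusted p = 1.04e-14), the sodium pump gene Atp1a4 (-2.14, chromosome 1), Inhbb (-1.67, chromosome 1; -3.01 with sh1 and -0.33 with sh2), the oxygen-sensing hydroxylase gene Egln3 (-1.63), the cysteine dioxygenase gene Cdo1 (-1.63) and the glycosyltransferase subunit gene Alg13 (-1.58, chromosome X; -2.92 with sh1 and -0.24 with sh2). Trim66 had 2 and 4 counts in the controls and 9, 17, 7 and 10 in the knockdown (log2 fold change 1.82, adjusted p = 0.0281). This call was lost in 6 of 13 alternatives, with an adjusted p up to 0.217.

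In the same contrast genes of chromosome 1 had a median of -0.26, with 370 of 756 lower, and genes of chromosome 19 of -0.28, with 259 of 480 lower. The Dax1 controls held chromosome 1 at 0.25 and 0.25 and chromosome 19 at 0.22 and 0.26 above the GFP libraries, relative to other autosomes, and the knockdown libraries lay at -0.08 to 0.05 on both. Of 5 Y-linked genes 4 rose. Without chromosomes 1, 15, 19 and Y, 2158 genes were higher and 1867 lower. With both hairpins treated as samples of 1 group 286 were higher and 298 lower, DESeq2 called 1314 higher, and upper quartile scaling moved the share of higher among called genes from 47.4% to 55.7%.

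The hairpins differed from each other in 2517 genes that were higher and 2664 that were lower with sh2, and in 185 and 42 elements. Nr0b1 was 0.36 higher with sh2, MERVL-int 1.02 lower, MT2_Mm 0.65 lower, Zscan4c 1.33 lower, Zscan4d 1.54 lower and Zfp352 1.40 lower on the log2 scale, and 39 of the 45 2-cell genes were lower with sh2 and 1 higher. The largest differences were those of Alg13 and Inhbb (2.68 each), Khdc3 (2.67) and the semaphorin gene Sema5b (2.49) on the higher side and of the caveolin gene Cav1 (-3.45), the collagen gene Col1a1 (-3.32), the desmosome gene Dsc2 (-3.06) and the mesoderm factor gene T (-2.98) on the lower side. Genes called with both hairpins shared 953 higher and 1094 lower, against 381 and 404 for independent lists and 0.1 and 0.2 in the simulation with shared controls. Without chromosomes 1, 15, 19 and Y, 877 and 665 were shared, against 369 and 240. The correlation across genes was 0.723 against 0.498 simulated, and the covariance 0.18 against 0.00464. Here too the 2 controls cannot be split, and part of the excess may come from them.

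The double knockdown asked whether the rise of 2-cell genes with lower DAX1 depends on Dux. No gene of the 2-cell list was called by edgeR among the 17 tested, against 9 higher over the list alone, 10 higher at an unadjusted p and 3 higher by DESeq2. Their summed level went from 23.7 to 44.8 CPM, with a median log2 fold change of 3.27, or 3.18 with 2 genes at their bound (camera adjusted p = 1.66e-07; adjusted p = 0.652 with an estimated correlation). MERVL-int went from 88.6 ± 19.1 to 176 ± 12.9 CPM (SD, n = 2 each), a log2 fold change of 0.99 (SE 0.183, adjusted p = 0.209), and MT2_Mm was at 0.30 (adjusted p = 0.477). Zscan4c was at 3.92 (adjusted p = 0.223) and Zscan4d at 1.64 (adjusted p = 0.566).

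Of the 13 genes that rose, 4 are Y-linked. The RNA helicase gene Ddx3y and the histone demethylase gene Uty had 0 counts in both controls and were at least 689-fold and 216-fold higher, the translation factor gene Eif2s3y rose by 6.99 (adjusted p = 0.0208) and the ubiquitin activating enzyme gene Uba1y by 5.58 (adjusted p = 0.0394). Others were Fmr1nb (5.48, adjusted p = 0.0102) and Cxx1b (2.38, adjusted p = 0.0474), both on chromosome X, the zinc finger gene Zfp951 (4.45, adjusted p = 0.0482), the IGF binding protein gene Igfbp4 (3.20, adjusted p = 0.00694) and Vim (1.87, adjusted p = 0.0482). Alg13 (-3.19, adjusted p = 0.0102) and the metal transporter gene Slc39a8 (-2.32, adjusted p = 0.0394) fell. Of 10 alternatives, 4 ended the call of Zfp951 (adjusted p up to 0.203). In 3 each the calls of Vim, Cxx1b, Uba1y and Slc39a8 were lost (adjusted p up to 0.211, 0.336, 0.15 and 0.246). Pou5f1, Sox2, Nanog and Zfp42 were at -0.37, -0.44, -0.44 and -0.27, none past the threshold (adjusted p = 0.535, 0.425, 0.507 and 0.582). Trim66 had 4 and 87 counts in the controls and 7 and 16 in the knockdown (-1.93, adjusted p = 0.568), and without the second control its log2 fold change was 1.59.

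Among the other lists, fibroblast genes had a median of 1.12: Vim was called, 11 of 21 were higher over the list alone, 13 at an unadjusted p and 5 by DESeq2 (camera adjusted p = 5.73e-11). Trophectoderm genes (0.81; 8.86e-06), interferon-stimulated genes (0.43; 3.88e-04), germ layer genes (0.63; 0.00228), cholesterol synthesis (0.19; 0.00251), p53 targets (0.12; 0.026) and primitive endoderm (0.27; 0.033) lay higher by camera. Ribosome biogenesis (-0.23; 3.3e-06), retroelement silencing (-0.23; 2.06e-05), glycolysis and hypoxia (-0.33; 0.00253), mitotic genes (-0.12; 0.00253), 2-cell regulators (-0.16; 0.00511), SINE B1 and B2 (-0.15; 0.00511), naive genes (-0.14; 0.0116), all LINE-1 (-0.12; 0.0125), ETn and MusD (-0.60; 0.019) and formative genes (-0.31; 0.026) lay lower, each given as median and camera adjusted p. With an estimated correlation each of these lists had an adjusted p = 0.652. Germline, oocyte, integrated stress and imprinted genes, genes linked to DAX1 and the other element classes gave no camera call.

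Over 13603 genes, 13 were higher and 2 lower, against 862 and 669 at an unadjusted p and 114 and 90 by DESeq2, and of 784 elements edgeR called 0, against 38 at an unadjusted p and 6 by DESeq2. Genes of chromosome 19 had a median of -0.50, with 0 calls among 472, and the controls held chromosome 19 at 0.48 and 0.49 above the GFP libraries. The control libraries decided these counts: without control replicate 1, 683 genes were higher and 512 lower, 13 2-cell genes rose and MERVL-int passed at 1.23 (adjusted p = 9.58e-20); without control replicate 2 the values were 2727, 2051, 10 and 0.79 (adjusted p = 2.12e-09). Without either knockdown library 5 and 1 genes were called.

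**Figure D3:**
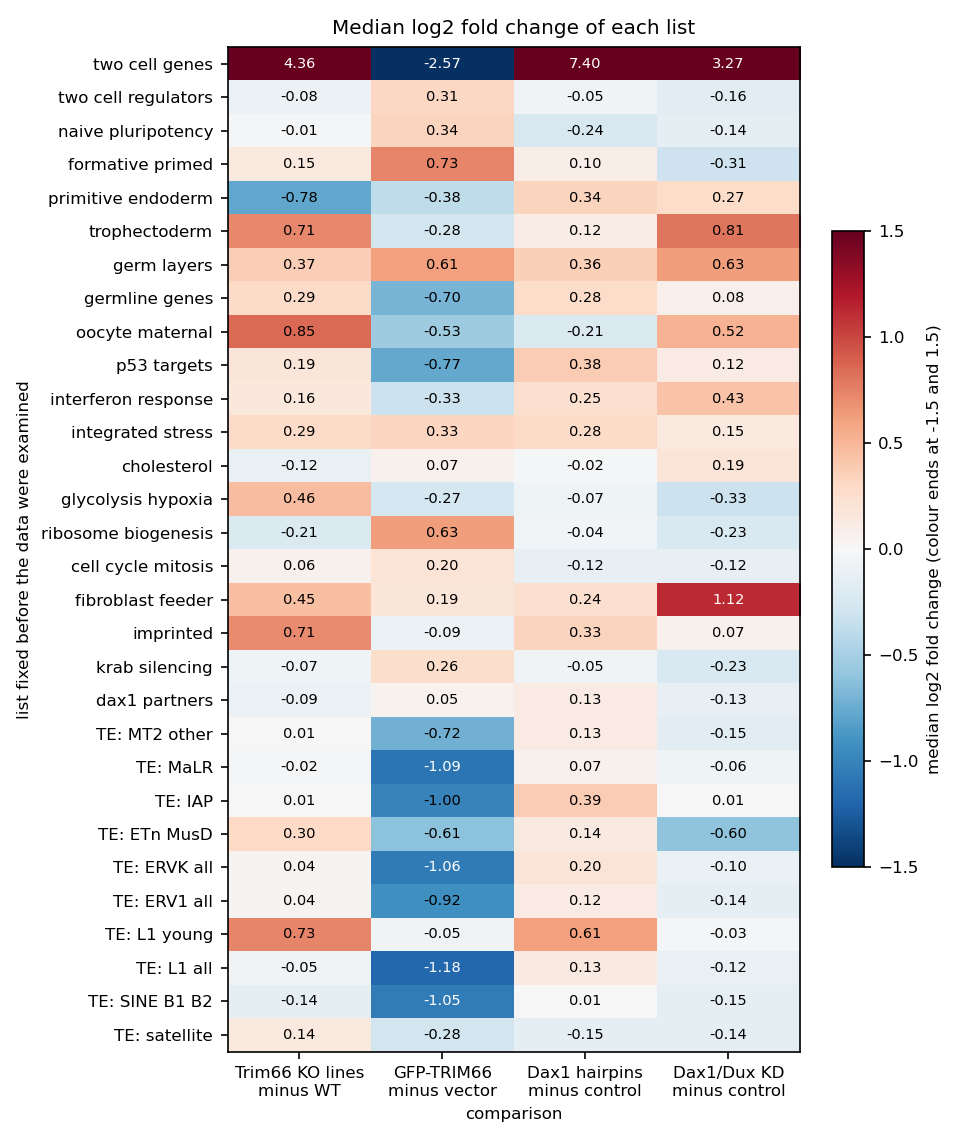
Median fitted log2 fold change of each list, with lists down the side and the 4 comparisons across, and colour ends at -1.5 and 1.5; medians of the 2-cell list include genes at 0 counts whose fitted values are not bounds. The 2-cell list stood at 4.36 in the libraries labelled Trim66 knockout, -2.57 with GFP-TRIM66, 7.40 in the Dax1 knockdown and 3.27 in the double knockdown.

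The Dax1 knockdown effect was then set against the double knockdown effect, each taken against its own controls in a fit over all 20 libraries. The double knockdown experiment had no knockdown of Dax1 alone, so a difference cannot be assigned to Dux apart from other differences between experiments. Nr0b1 had 680 and 444 counts in the controls of the double knockdown and 2242 and 2179 in those of the Dax1 knockdown. The 2-cell genes rose more in the single than in the double knockdown. Of 45 tested, 4 differed after adjustment over all genes, all higher in the single knockdown, and 17 adjusted over the list alone (camera adjusted p = 2.8e-67, and adjusted p = 6.78e-05 with an estimated correlation). They were Zscan4a (log2 difference 6.78, adjusted p = 0.0156), Zscan4b (6.95, adjusted p = 0.0295), Zscan4d (6.90, adjusted p = 0.014) and Zscan4f (5.60, adjusted p = 0.0156), while Zscan4c, at 5.87, did not pass (adjusted p = 0.125). Of 17 alternatives, 6 ended the call of Zscan4a, 10 that of Zscan4b, 5 that of Zscan4d and 4 that of Zscan4f, which also turned in 1 more. Without control replicate 1 of the double knockdown they were at 0.59, 1.51, 1.32 and -0.10. MT2_Mm differed by 2.06 (SE 0.231, adjusted p = 8.86e-04) and MERVL-int by 1.84 (SE 0.375, adjusted p = 0.044). The MERVL-int call was lost in 11 of 16 alternatives, at log2 differences of 1.61 to 2.03, and that of MT2_Mm in 1.

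The fall of Nr0b1 was at a log2 difference of -0.31 between the experiments (adjusted p = 0.905). In all 15 genes had a higher and 40 a lower effect in the single knockdown, with 5 and 2 elements, or 14 and 30 genes without chromosomes 1, 15, 19 and Y. On the lower side stood Ddx3y (-7.13), Uty (-6.68) and Eif2s3y (-3.51), all Y-linked, and the myelin protein gene Pmp22 (-3.56). Of 17 alternatives, 4 ended the call of Ddx3y, 12 that of Uty, 1 that of Eif2s3y and 6 that of Pmp22. Fibroblast and trophectoderm genes lay lower as lists (camera adjusted p = 2.78e-06 and 6.02e-06; adjusted p = 0.328 and 0.433 with an estimated correlation). ERVK elements, ETn and MusD, all LINE-1 and other MT2 elements lay higher (2.78e-06, 6.99e-05, 2.06e-05 and 0.00329; adjusted p = 0.507, 0.328, 0.653 and 0.433 with an estimated correlation). Left-out control libraries moved the counts of genes, as given below. When hairpins were treated as samples of 1 group edgeR called 0 genes.

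The series title places TRIM66 and DAX1 on 1 axis, and genes called in both experiments, with separate controls, were counted. Of 13572 genes tested in both, 628 were higher in both, against 290 for independent lists (odds ratio 3.52, one-sided Fisher's exact p = 1.29e-100), and 720 were lower in both, against 299 (odds ratio 4.61, p = 1.49e-150). Opposite directions held 208 and 132 genes, against 342 and 253. Of the 33 2-cell genes tested in both, 28 rose in both. Without chromosomes 1, 15, 19 and Y, 572 higher and 394 lower genes were shared, against 268 and 167. Pooling lines and hairpins left 48 and 32. The p-values treat genes as independent. An effect on other genes of the higher chromosome 1 level in both control groups stays open.

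Genes raised in the libraries labelled Trim66 knockout were also followed as a set. In the Dax1 knockdown the set lay higher (median log2 fold change 0.17, camera adjusted p = 3.91e-08, and adjusted p = 9.8e-04 with an estimated correlation). In the double knockdown it lay higher (0.20; 9.18e-07, and adjusted p = 0.118 with an estimated correlation), and with GFP-TRIM66 lower (-0.31; 1.13e-05, and adjusted p = 0.22 with an estimated correlation). The set raised in the Dax1 knockdown lay higher in the double knockdown (0.19; 4.79e-11, and adjusted p = 0.0345 with an estimated correlation) and gave no call with GFP-TRIM66 (-0.05; 0.544). Lowered sets, which include genes of chromosomes 1 and 19, were tested too. The set lowered in the Dax1 knockdown lay higher with GFP-TRIM66 (0.19; 2.39e-08, and adjusted p = 0.102 with an estimated correlation) and lower in the double knockdown (-0.17; 1.72e-13, and adjusted p = 0.0354). The set lowered in the libraries labelled knockout lay higher with GFP-TRIM66 (0.31; 1.95e-12, and adjusted p = 0.163), and lower in the Dax1 knockdown (7.81e-15, and adjusted p = 0.0102) and the double knockdown (-0.11; 2.08e-04, and adjusted p = 0.118). Of the 13 genes that rose in the double knockdown 12 also rose in the Dax1 knockdown, against 2.13 for independent lists (odds ratio 61.7, one-sided Fisher's exact p = 3.97e-09). Of these 12 genes 4 are Y-linked and were low in both control groups. Without chromosomes 1, 15, 19 and Y 8 genes rose in the double knockdown.

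**Figure D4:**
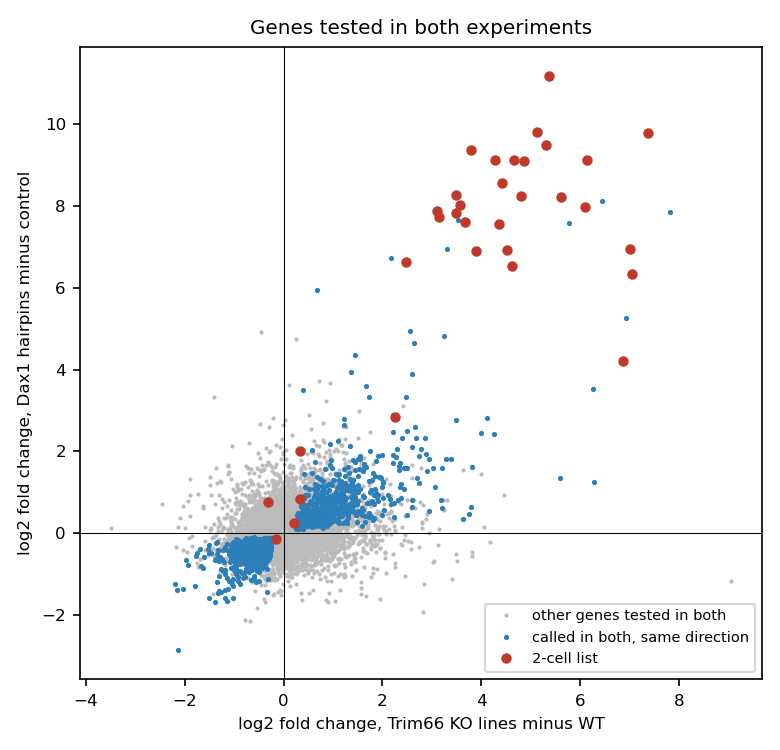
Log2 fold change of 13572 genes in the libraries labelled Trim66 knockout (x axis) and in the Dax1 knockdown (y axis), with blue points for the genes called in the same direction in both and red points for 33 genes of the 2-cell list; fitted values of genes at 0 counts are not bounds. Of the red points 31 lie above 0 on both axes.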

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

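All tests in this part were chosen before the result they measure was seen, except the tests on cells with a Y chromosome and on loss of TRIM66. The differences listed first stand here because the effects of a pair of lines, hairpins or experiments differed by a test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg).

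KO2 and KO1 differed in 1465 genes higher and 1941 lower in KO2, and KO2 held more RNA of the 2-cell state, with log2 differences of 0.67 for MERVL-int, 0.62 for MT2_Mm, 1.92 for Zscan4c, 2.64 for Zscan4d and 2.00 for Zfp352. Hairpin 2 and hairpin 1 differed in 2517 genes higher and 2664 lower with hairpin 2. Hairpin 2 left more Nr0b1 (0.36) and gave less MERVL-int (-1.02), MT2_Mm (-0.65), Zscan4c (-1.33), Zscan4d (-1.54), Zfp352 (-1.40) and Dux (-1.21). The Dax1 knockdown effect was higher than the double knockdown effect for 15 genes and lower for 40, with log2 differences of 1.84 for MERVL-int, 2.06 for MT2_Mm and 6.90 for Zscan4d. The cause of these differences was not tested.

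The first pattern weighed was the lower RNA from genes of chromosome 1 in the libraries labelled Trim66 knockout. A trend with expression level or gene length was excluded, since 530 genes of other autosomes matched on both had a median log2 fold change of -0.04. A response of 1 part of the chromosome was excluded for the mean of both lines, where the highest median among its stretches was -0.34, although in KO2 alone the last 2 stretches lay at -0.12 and -0.03. The wild-type libraries stood at least 0.53 above the GFP libraries on this chromosome and the libraries labelled knockout near 0, which is consistent with an extra copy in the wild-type culture. The 12 libraries of other experiments in which Trim66 was not targeted stood at most 0.25 above the GFP libraries. This argues against loss of TRIM66 as the whole cause, which would place them near the wild-type level. It does not exclude that cause, since the experiments may differ in other ways. The GFP vector libraries among the 12 are part of the reference and lie near 0 by construction. A smaller part played by TRIM66 was not tested and stays open.

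The next was the near absence of RNA from Y-linked genes in both Dax1 control groups. The Y-linked gene with the highest control level, Eif2s3y in the Dax1 experiment, reached 7.84% of its knockdown level there. This value restates the pattern, so few cells with a Y chromosome in the controls cannot be told apart from other explanations. Reads moved to the X-linked homologues stay open. These homologues held 292 CPM more in the double knockdown controls than in the knockdown, against 157 CPM lost from the Y-linked genes, with an SD of 103 CPM between the controls. In the Dax1 experiment the X-linked homologues held 123 CPM more in the controls, against 90.5 CPM lost, with an SD of 10.2 CPM between the controls. The labels do not say whether controls and knockdowns came from the same culture.

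The last was the lower RNA of transposable elements with GFP-TRIM66. Lower RNA of LTR retroelements alone was excluded, since their median differed from that of old, inactive elements by 0.09 and each old class was lower too. The size of the difference depended on the old class. ERVK, ERV1 and ERVL together lay at -1.04, against -1.24 for hAT and TcMar, -0.71 for L2 and CR1 and -0.67 for MIR. A larger fall of LTR retroelements than of L2, CR1 and MIR was thus not excluded. The old elements had a median of -1.13 themselves, which is consistent with more reads from introns or genomic DNA in the vector libraries. Repression by TRIM66 of all classes was not tested and stays open.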

How the results depend on the processing

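Leaving out chromosomes and crossing the replicate numbers were chosen after the data were seen; the other alternatives were planned. Of 2062 values of named genes past the threshold, 1921 kept direction and side of the threshold, 140 lost the call and 1 turned: Zscan4f between the knockdowns, -0.10 without control replicate 1 of the double knockdown, where the other control holds 0 counts, in a range up to 6.55. Pooling lines or hairpins, which adds their difference to the spread, ended 56 of 124 such calls. It left 276 higher and 264 lower genes in the libraries labelled Trim66 knockout, 14 of the 2-cell list, MERVL-int at 0.72 (adjusted p = 0.127) and MT2_Mm at 0.45 (adjusted p = 0.282), 286 and 298 genes in the Dax1 knockdown, 48 and 32 shared genes, and 0 and 0 between the knockdowns. A minimum fold change of 2 left 767 and 224 (knockout), 395 and 612 (lines), 604 and 108 (Dax1), 223 and 932 (hairpins) and 159 and 23 (shared), by construction. DESeq2 gave 288 and 111 with GFP-TRIM66, with 8 2-cell genes lower, 1314 higher in the Dax1 knockdown, 1654 and 1599 between hairpins, 114 and 90 in the double knockdown, with 3 2-cell genes and MERVL-int at 0.98 (adjusted p = 0.00316), 341 shared higher genes, and 53 and 107 between the knockdowns. With no filter the counts were 15 and 4 (GFP-TRIM66) and 53 and 137 (between the knockdowns), with upper quartile scaling 22 lower in the latter, and with genes only or without 4 chromosomes 8 higher in the double knockdown; the latter left 394 shared lower genes. Upper quartile scaling moved the median of all genes by -0.13 with GFP-TRIM66. The cause was not tested.

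The replicate block gave 5 higher and 1 lower gene in the double knockdown. Deviations of same-numbered libraries correlated at 0.187, 0.451, 0.088, -0.641, 0.038, -0.031, 0.163 and 0.038. The value of 0.451 belongs to wild type and KO2. That of -0.641 belongs to the vector and GFP-TRIM66, where replicate 1 of each group deviated with replicate 2 of the other. The numbers thus did not pair the samples in a uniform way, and shared deviations remain in these pairs of groups. Crossed pairing with GFP-TRIM66 gave 2162 higher and 1403 lower genes. It was chosen from these deviations, so this count is no test.

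For the 2-cell list an estimated correlation gave adjusted p = 0.0593 (knockout), 0.477 (GFP-TRIM66) and 0.652 (double knockdown), and fry 0.111 and 0.197 in the last 2. The set raised in the libraries labelled knockout then had a camera adjusted p = 0.22 with GFP-TRIM66 and 0.118 in the double knockdown. Over the lists in the 4 comparisons with controls, 60 of 62 camera calls ended with an estimated correlation and 39 with fry. With RLE scaling or the block 0 ended, where lists with a camera call and the 2-cell list were recomputed. The 2-cell list (knockout) lost its call at an estimate of -0.0189, and germ layer genes (double knockdown) at -0.0258. Both estimates lie below the preset, while others lie above it, such as young LINE-1 (knockout) at 0.454. An ended call thus cannot tell correlation between genes from an effect of the setting itself.

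With 1 library left out, the lone sample was assumed to vary like the others. Counts of higher and lower genes ranged from 674 to 2646 and 528 to 2684 in the knockout comparison (674 and 528 without wild-type replicate 1, 689 and 703 without replicate 2, 1047 and 884 without KO1 replicate 1, 1024 and 821 without KO1 replicate 2, 2684 lower without KO2 replicate 2), with 20 to 29 2-cell genes, MERVL-int at 0.63 to 0.74, and MT2_Mm at 0.38 to 0.45, not called without wild-type replicate 1 (0.40) or 2 (0.41) or KO1 replicate 2 (0.38). With GFP-TRIM66 they ranged from 8 to 391 and 2 to 290 (8 and 2 without vector replicate 1, 391 and 79 without replicate 2, 50 and 16 without GFP-TRIM66 replicate 1, 371 and 290 without replicate 2), with 0 to 5 2-cell genes lower (1 without vector replicate 2, 2 and 5 without GFP-TRIM66 replicate 1 and 2) and MERVL-int at -1.58 to -0.34, called without GFP-TRIM66 replicate 1. The Dax1 knockdown gave 1513 to 2177 and 1742 to 2445 (1536 and 1513 higher without control replicate 1 or 2), and the double knockdown 5 to 2727 and 1 to 2051 (683 and 512 without control replicate 1, 2727 and 2051 without control replicate 2, 5 and 1 without either knockdown library), with 0 to 13 2-cell genes and MERVL-int at 0.79 to 1.23 (13 and 1.23 without control replicate 1, 10 and 0.79 without replicate 2, both MERVL-int values called). Between lines they ranged from 366 to 2362 and 583 to 2977 (370 and 583 without KO1 replicate 1, 366 and 610 without KO1 replicate 2, 2362 and 2977 without KO2 replicate 2), between hairpins from 1963 to 2415 and 2042 to 2655, for shared genes from 279 to 792 and 321 to 1052 (282 and 321 without wild-type replicate 1, 279 and 414 without replicate 2, 399 and 453 without KO1 replicate 2), and between the knockdowns from 0 to 170 and 4 to 649 (3 and 7 without Dax1 control replicate 1, 0 and 4 without replicate 2, 9 and 12 without hairpin 1 replicate 1, 17 lower without replicate 2, 9 and 10 without hairpin 2 replicate 1, 18 lower without replicate 2, 21 lower without double knockdown control replicate 1, 170 and 649 without replicate 2, 6 and 8 without double knockdown replicate 1, 2 and 7 without replicate 2). The sign turned for values near 0: Sox2 in the knockout comparison (-0.01 with RLE, no filter and DESeq2, 0 with the block and genes only, -0.12 to 0.10 with libraries left out), Pou5f1 (-0.33 to 0.07) and Zfp42 (-0.10 to 0.04) there with libraries left out, Pou5f1 in the Dax1 knockdown (0 with RLE, -0.01 with no filter and DESeq2, -0.02 to 0.02 with libraries left out). It also turned for Trim66 in the double knockdown, which was at -1.93 with all libraries and not near 0 (-2.86 to 1.59, the latter without control replicate 2). Depth limits what the 2-cell genes can show, since Dux and Zfp352 had under 100 counts in every library.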

Other observations

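The lists and the tests of lines and hairpins in this part were set before the data were seen, while the values described and the division of chromosome 15 into stretches were chosen afterwards. Germline genes, which most other cells hold methylated and silent, moved apart between the lines labelled Trim66 knockout. Of 29 tested, 4 rose and 12 fell in KO1 (camera adjusted p = 0.0218, and adjusted p = 0.679 with an estimated correlation), while 16 rose and 0 fell in KO2 (3.7e-09, and adjusted p = 0.343). The difference itself was called for 22 higher and 1 lower gene in KO2 by edgeR (camera 2.07e-15, and adjusted p = 0.308). Integrated stress genes were higher in KO1, with 23 rises and 0 falls of 35, and 17 of them were lower in KO2 than in KO1 (1.83e-07, and adjusted p = 0.11). Mitotic genes were higher in KO2 than in KO1 in 16 of 30 cases (3.7e-06, and adjusted p = 0.391), and fibroblast genes lower in 10 of 17 and higher in 1 (0.00153, and adjusted p = 0.308).

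Hairpin 2 left naive pluripotency genes higher than hairpin 1, in 33 of 40 cases with 1 lower (median log2 difference 0.36, camera adjusted p = 7.57e-21, and adjusted p = 0.0427 with an estimated correlation). Genes of fibroblasts (1 higher and 17 lower of 20, median -1.47), trophectoderm (3 and 11) and imprinted genes (2 and 18) were lower with hairpin 2 (camera adjusted p = 2.36e-11, 5.3e-06 and 3.83e-06, and adjusted p = 0.079 for each with an estimated correlation). SINE B1 and B2 were higher in 18 of 21 cases (camera adjusted p = 3.46e-08, and adjusted p = 0.341 with an estimated correlation).

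Alg13, a glycosyltransferase subunit gene, was at a log2 fold change of -2.92 with hairpin 1, -0.24 with hairpin 2 and -3.19 in the double knockdown. Inhbb was at 2.59 with GFP-TRIM66 and -1.67 in the Dax1 knockdown. Trim66 had 4 and 87 counts in the controls of the double knockdown. Kdm5d, on the Y chromosome, had 0 to 4 counts in every library. The last 2 stretches of chromosome 15 lay at 0.65 and 0.55 in KO1.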
